A study of Homo sapiens with 9 samples.

How the data were processed

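RNA abundance was measured with microarrays in MDA-MB-231, a triple-negative breast cancer cell line (a line that lacks the estrogen and progesterone receptors and HER2 amplification). Per the labels, total RNA was taken from 3 samples with no agent at time 0, from 3 treated with 500 nM JQ1 for 12 h and from 3 treated with 500 nM JQ1 for 24 h, and each sample was hybridised to its own Affymetrix Human Gene 2.0 ST array. JQ1 is a small molecule that occupies the acetyl-lysine pocket of the bromodomains of the BET proteins and displaces them from chromatin. The labels name no vehicle for the controls and give them a single time, so the controls are matched to neither treatment time. A difference between treated and control arrays can therefore hold an effect of solvent or of time in culture beside that of JQ1. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

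The authors deposited 1 table of processed values with 53617 rows and 9 columns, 1 column per array, and no scanner files, detection calls, slides or scan dates were used here. The unit was taken as log2 from the deposited values themselves. They ran from 2.01 to 13.88, with array medians between 4.92 and 4.96. On a log2 scale the highest reading corresponds to 15077 intensity units, under the 65535 of a 16-bit scanner, whereas on a natural log scale it would correspond to 1066720. The values were not centred per gene. Per the submitters' processing notes, Transcriptome Analysis Console was used; its version is not given in the sources used here, nor are the background correction, the normalization and the summarisation of probes. Arrays whose quartiles lie this close have usually been normalized against each other, and such a step removes any change in the total amount of RNA per cell. Statements about genes that rose or fell are therefore relative to the other genes on the array. The 9 arrays and their 3 per group limit the precision.

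Rows were named through the platform's gene table. Of the 53617 rows, 16098 had exactly 1 gene symbol, 0 had several and 37519 are unnamed here. The unnamed rows were dimmer, with a median of 4.50 against 6.07 for the named rows. All 16098 named rows matched the RefSeq gene table of assembly GRCh38.p14 by gene ID, and 0 symbols needed updating. No genome build is given in the sources used here for the array, so no coordinates are printed and the gene table was used only for names and for the order of genes along chromosomes. Of the genes, 779 had more than 1 row. The row with the highest mean over the 9 arrays stood for the gene, which left 14884 genes. Rows of 1 gene did not always give the same answer. For VIM the row used was not called in either comparison with control, while its 2 other rows were called in both. For HEXIM1 a dim second row was called at 24 h and not at 12 h, while the row used was called at both.

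Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 9 arrays, so that the 3 groups shared 1 estimate of the spread per gene, followed by empirical Bayes moderation without trend, with 3.14 prior degrees of freedom. P-values were adjusted over the 14884 genes with the Benjamini-Hochberg method within each of 3 comparisons, JQ1 12 h against control, JQ1 24 h against control and JQ1 24 h against JQ1 12 h. A gene was called at an adjusted p under 0.05. No filter on dim genes was applied. Every adjusted p of a gene given in the text comes from this fit unless another is named. Differences are on the log2 scale with the standard error (SE) of the moderated fit, and group values are means with SD over 3 arrays. Principal components were computed on the genes tested.

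Before the data were examined, 22 gene lists were fixed, of which 21 had at least 5 measured members and were tested. The list of replication-dependent histones had none of its members among the named rows and was not analysed here. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, which asks whether a list's genes shifted against the other genes, with Benjamini-Hochberg adjustment over the lists within a comparison. The same test was run with the correlation estimated from the data. None of the list calls of any comparison held with an estimated correlation. The rotation test fry was run beside it. It asks whether a list's genes moved on balance one way, or in either direction in its mixed form, and does not compare the list with other genes. Members past the threshold were counted over all genes tested and after adjustment over the list alone.

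The genes named in the text follow a rule fixed before the data were examined. It takes, for each comparison with control, the 10 genes with the highest and the 10 with the lowest log2 difference among those called whose groups did not overlap, leaving out uncharacterised loci, small RNAs, antisense transcripts, olfactory receptors and pseudogenes. For 24 h against 12 h it takes 5 and 5. It adds 18 genes fixed by name, of which 14 were measured, and the 2 to 4 members of each list with the lowest p. The other fixed genes are not analysed here. Genes named outside this rule are said to be so.

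The procedure was tested on simulated data with 14884 genes drawn with the spread of the real arrays and 200 genes changed by known amounts. The noise was drawn independently for each gene and array, with 1 spread per gene for all groups. Deviations that many genes of 1 array share, such as those of control 3, were not simulated. The shares below may therefore not hold for the real arrays. For JQ1 12 h against control it recovered 42% of changes of 0.5 log2, 84% of changes of 1, 94% of changes of 1.5 and 98% of changes of 2, and 3.64% of its calls were false. For JQ1 24 h against control the shares were 58%, 82%, 98% and 100%, with 3.43% of calls false. A missed call for a change of 0.5 log2 therefore says little about whether that gene changed.

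The alternatives fixed in advance were a filter that drops the genes with the lowest means, all rows of the table in place of 1 per gene, the mean of all rows of a gene, quantile normalization, centring each array on its median, moderation with trend and robust estimation, array weights, a linear model without moderation, a fit of only the 2 groups compared, the replicate number as a block, a threshold of 0.01 on the adjusted p, and leaving out each of the 9 arrays in turn. Counts of list members without control 3 were added after its distance from controls 1 and 2 had been seen. The correlation and covariance of the 12 h and 24 h differences were set against 100 simulated data sets in which no group differed, made by shuffling the 9 arrays' deviations from their group means with random signs. Other splits of the 6 arrays of each comparison into 3 and 3 were refitted in the same way. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.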

Results

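The series was made to help choose BET bromodomain inhibitors for triple-negative breast cancer. Its arrays address which genes change in MDA-MB-231 cells after 12 h and 24 h of 500 nM JQ1. Log2 array values were compared for 3 control, 3 JQ1 12 h and 3 JQ1 24 h arrays, over 14884 named genes. Array medians lay between 4.92 and 4.96 and no pair of arrays held identical values.

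The treated arrays separated from the controls, but 1 control stood apart. Controls 1 and 2 correlated at r = 0.9948 across all rows of the table, and their values differed with an SD of 0.213 log2. Control 3 correlated with them at 0.9832 and 0.9828, with SDs of 0.385 and 0.389, as far from them as several treated arrays were. It lay nearer to JQ1 12 h replicates 2 (r = 0.9888, SD 0.314) and 3 (0.9866, 0.343) and to JQ1 24 h replicate 2 (0.9856, 0.355). Its SDs were 0.388 from JQ1 12 h replicate 1 and 0.398 and 0.404 from JQ1 24 h replicates 1 and 3. Pairs within the 2 treated groups had SDs between 0.2499 and 0.297. Rows of an array are not independent replicates, so these correlations only describe the arrays. The first principal component held 49.3% of the variance and separated controls 1 and 2 from the treated arrays. The second held 23.2% and set control 3 (score −33.0) apart from all the others. Across the gene lists, the median member of the DNA replication list was 1.16 log2 higher in control 3 than in the mean of controls 1 and 2 (26 of 26 members higher), and the median member of the unfolded protein and integrated stress response list was 1.58 lower (14 of 15 members lower). The numbers of genes called are therefore also given without control 3, as are values of many of the lists.

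**Figure D1:**
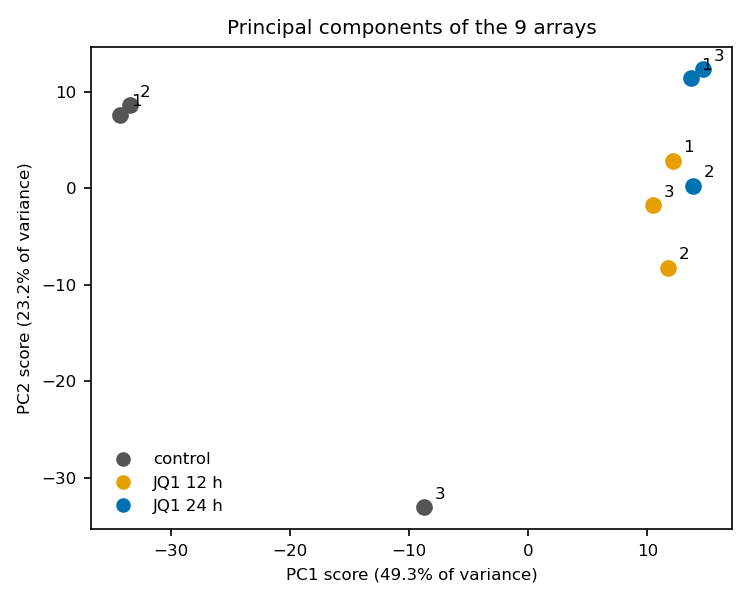
Scores of the 9 arrays on the first 2 principal components (x axis 49.3% and y axis 23.2% of the variance), coloured by group and numbered by replicate. The 6 treated arrays lie to the right, controls 1 and 2 to the left, and control 3 lies by itself at a PC2 score of −33.0.

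After 12 h of JQ1, BRD2, a BET protein that JQ1 binds, rose from 8.42 ± 0.04 to 9.47 ± 0.02 (SD, n = 3 each), a 2.07-fold change (log2 difference 1.05, SE 0.06, adjusted p = 9.9e-05). HEXIM1, an inhibitor of the transcription elongation factor P-TEFb, rose 3.46-fold (log2 1.79, SE 0.20, adjusted p = 0.0017). The highest rise was that of EFR3B, a membrane scaffold for a phosphatidylinositol kinase, from 5.61 ± 0.35 to 8.86 ± 0.14, or 9.55-fold (log2 3.26, SE 0.16, adjusted p = 3.0e-05). FST, which encodes the activin-binding protein follistatin, fell from 9.20 ± 0.19 to 6.34 ± 0.10, a 7.27-fold lower value (log2 −2.86, SE 0.13, adjusted p = 3.0e-05). The zinc finger gene ZNF532 fell 4.82-fold (log2 −2.27, SE 0.08, adjusted p = 7.2e-06). MYC, the proto-oncogene most often tied to BET inhibition, fell 1.95-fold (log2 −0.96, SE 0.19, adjusted p = 0.019); it was 10.29 and 10.32 in controls 1 and 2, 9.52 in control 3 and 9.08 ± 0.11 in the treated arrays.

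Other genes among the 10 highest rises at 12 h were the stress-inducible sestrin SESN3 (log2 2.65), the imprinted retrotransposon-derived gene PEG10 (2.52), the metallothionein MT1E (1.59), PCYOX1 (1.54), MIDN (1.49), MYLIP, a ubiquitin ligase for the LDL receptor (1.47), and the HSP70 genes HSPA1B (1.53) and HSPA1A (1.44), which are near-identical copies that the probes may not separate. Among the 10 strongest falls were the matrix glycoprotein TNC (log2 −2.82), the cytokine LIF (−2.72), endothelin-1 (EDN1, −2.26), the circadian regulator PER2 (−2.13), CD22 (−2.11), the homeobox gene HOXB9 (−2.09), MPZL3 (−2.03) and thrombomodulin (THBD, −2.02). Adjusted p-values of these 16 genes ran from 0.00011 for SESN3 to 0.033 for TNC. Of all 64 genes named and called at 12 h, 31 kept the call whichever single array was left out. TNC lost it when any array but control 3 was left out (adjusted p up to 0.11), and PER2, HOXB9, HSPA1B and MYC lost it without control 1, control 2 or any of the JQ1 12 h arrays (up to 0.065, 0.059, 0.071 and 0.074). THBD lost it without any of those 5 arrays or JQ1 24 h replicate 3 (up to 0.098), and HSPA1A without control 1 or any JQ1 12 h array (up to 0.054). Without control 3 all of these were called, TNC at log2 −3.80 and MYC at −1.22.

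In total 1181 genes were called at 12 h, 527 up and 654 down, and 177 of them changed at least 2-fold (60 up, 117 down). In all 1181, the 3 treated values lay on 1 side of the 3 control values; over all genes tested this held for 22.2%, against 10% by chance. Without control 3 the count was 2986 (1424 up, 1562 down), which included 1174 of the 1181. Without control 1 or control 2 it was 543 or 564, and without JQ1 12 h replicate 1, 2 or 3 it was 606, 566 or 605.

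The NF-kB and inflammatory cytokine list shifted down at 12 h (median log2 −0.58 over 20 members, camera adjusted p = 0.00011, and adjusted p = 0.58 with an estimated correlation). Of its members 0 rose and 5 fell (0 and 7 adjusted over the list alone), among them LIF, NFKB1 (log2 −0.56), CSF1 (−1.06) and CXCL2 (−0.69). CXCL8, interleukin 8, stood at 9.15, 8.94 and 5.17 in controls 1, 2 and 3 and at 5.28 ± 0.76 at 12 h, and was not called (log2 −2.47, SE 0.94, adjusted p = 0.16). Without control 3 the list's median was −1.04, and 15 members fell and 1 rose. The unfolded protein and integrated stress response list also shifted down (median −0.73 over 15 members, adjusted p = 0.0027, and 0.66 as adjusted p with an estimated correlation), although only PSAT1, a serine synthesis enzyme (log2 −1.23), was called over all genes, and 0 rose and 3 fell adjusted over the list alone. Control 3 was lower than controls 1 and 2 on this list by more than the treated arrays' shift. Without control 3 the list's median was −1.32, and 13 members fell and 1 rose.

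The MYC and MYC target list shifted down (median −0.22 over 19 members, adjusted p = 0.0047, and adjusted p = 0.58 with an estimated correlation). Beside MYC the members that fell included the ribosome biogenesis genes RRP12 (log2 −0.58) and WDR43 (−0.78) and the cell cycle kinase CDK4 (−0.58); 5 fell and 0 rose over all genes, and 6 fell and 1 rose adjusted over the list alone. Control 3 was higher than controls 1 and 2 on this list by a median of 0.52, and without control 3 the list's adjusted p was 0.27 (median −0.04). The p53 target and CDK inhibitor list shifted up (median 0.61 over 10 members, adjusted p = 0.00012, and adjusted p = 0.40 with an estimated correlation), with 4 members up over all genes and 5 adjusted over the list alone. Without control 3 the median was 0.36 and the adjusted p 0.022, with 4 members up and 1 down. The members called were SESN3, SESN1 (log2 0.99), CCNG1 (0.68) and PLK2 (0.63). Of these, the sestrins act in stress signalling and MDA-MB-231 carries mutant p53. SESN2, another sestrin of the list named here outside the rule, was not called and lay lower in the JQ1 arrays than in controls 1 and 2. It stood at 10.03, 9.98 and 6.74 in controls 1, 2 and 3 and had a mean of 7.46 over the JQ1 arrays of both times.

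Hypoxia and glycolysis genes shifted up at 12 h (median 0.41 over 15 members, adjusted p = 0.00078, and adjusted p = 0.40 with an estimated correlation), with BNIP3 (log2 0.83), ADM (0.86) and GAPDH (0.42) called; adjusted over the list alone 9 rose and 2 fell. Without control 3 the median was 0.25 and the adjusted p 0.029, with 5 members up and 2 down. VEGFA, a member named here outside the rule, was not called and went the other way. It stood at 9.43, 9.79 and 7.20 in controls 1, 2 and 3 and had a mean of 7.25 over the JQ1 arrays of both times. Cholesterol synthesis genes shifted up (median 0.36 over 17 members, adjusted p = 0.0047, and adjusted p = 0.60 with an estimated correlation), with MVD, an enzyme of the mevalonate pathway (log2 0.85), as the only member called, over all genes and adjusted over the list alone. Without control 2 that list's adjusted p was 0.054. Without control 3 its median was 0.54 and 11 of its members rose. Control 3 was higher than controls 1 and 2 on this list by a median of 0.71.

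The other 15 lists were not called at 12 h. The BET family and P-TEFb list had 3 of 10 members up, BRD2, HEXIM1 and MEPCE (log2 0.50), and 0 down, the same adjusted over the list alone (camera adjusted p = 0.090, 0.041 without control 1, and 0.40 with all arrays and an estimated correlation). By the rotation test fry, which does not set a list against other genes, this list was called up (fry adjusted p = 0.00072), as were the p53 (0.010) and hypoxia (0.010) lists, and 0 of the others in a single direction. BRD3 did not pass the limma test (log2 −0.01, SE 0.09). The interferon-stimulated list (25 members, adjusted p = 0.055) had 5 members down and 0 up (7 and 0 adjusted over the list alone), led by CD274, which encodes the immune checkpoint ligand PD-L1 (log2 −1.74, SE 0.23, adjusted p = 0.0031) and IFI44 (−1.01). It was called without control 3, JQ1 12 h replicate 1 or JQ1 12 h replicate 3 (adjusted p 0.018, 0.046 and 0.016 at the preset correlation, and 0.66 with all arrays and an estimated correlation). In the AP-1 and immediate early list (24 members, adjusted p = 0.64) KLF2 (log2 1.37), DUSP4, a MAP kinase phosphatase (0.95), IER5 (0.60) and JUND (1.05) rose and 1 member fell, the same counts as adjusted over the list alone. Without control 3 this list shifted down (adjusted p = 0.033 at the preset correlation, 10 members down and 4 up; with all arrays and an estimated correlation the adjusted p was 0.93). In the apoptosis list (17 members, adjusted p = 0.23), 3 members rose and 4 fell, 4 and 4 adjusted over the list alone. The falls included the anti-apoptotic genes BCL2A1 (log2 −1.62) and CFLAR (−0.92) and the rises APAF1 (0.57) and the pro-apoptotic BCL2L11 (0.85, adjusted p = 0.040, lost without any array but control 3, up to 0.14).

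For the remaining lists at 12 h the camera adjusted p-values were 0.88 for DNA replication (26 members, 0 called), 0.58 for mitosis (32 members, HMMR down), 0.58 for homologous recombination (15 members, 0 called), 0.081 for mesenchymal genes (16 members, TNC and ZEB2 down), 0.41 for epithelial and luminal genes (23 members, 1 up and 3 down), 0.17 for matrix proteases (15 members, 3 up and 1 down), 0.51 for integrins (8 members, FERMT1 down), 0.51 for YAP and TEAD targets (15 members, 2 up and 1 down), 0.44 for autophagy (20 members, 0 called), 0.58 for leukocyte markers (9 members, 0 called) and 0.33 for housekeeping genes (8 members, GAPDH up). Adjusted over the list alone, the matrix protease list had 3 up and 4 down, the mesenchymal list 1 and 4, the epithelial list 2 and 4, the integrin list 1 and 1, the YAP list 4 and 5, and the housekeeping list 1 and 0, while the DNA replication, mitosis, homologous recombination, autophagy and leukocyte lists had 0 and 0. Within the matrix protease list the inhibitor TIMP2 rose (log2 0.60) and MMP16 fell (−0.67). Without control 3 the DNA replication list shifted up at 12 h (adjusted p = 2.4e-05, 13 members up and 1 down), as did homologous recombination (adjusted p = 0.033), while matrix proteases and mesenchymal genes shifted down (0.0029 and 0.033). An estimated correlation was not tried without control 3; with all arrays it gave these 4 lists adjusted p-values of 0.97, 0.93, 0.66 and 0.40.

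**Figure D2:**
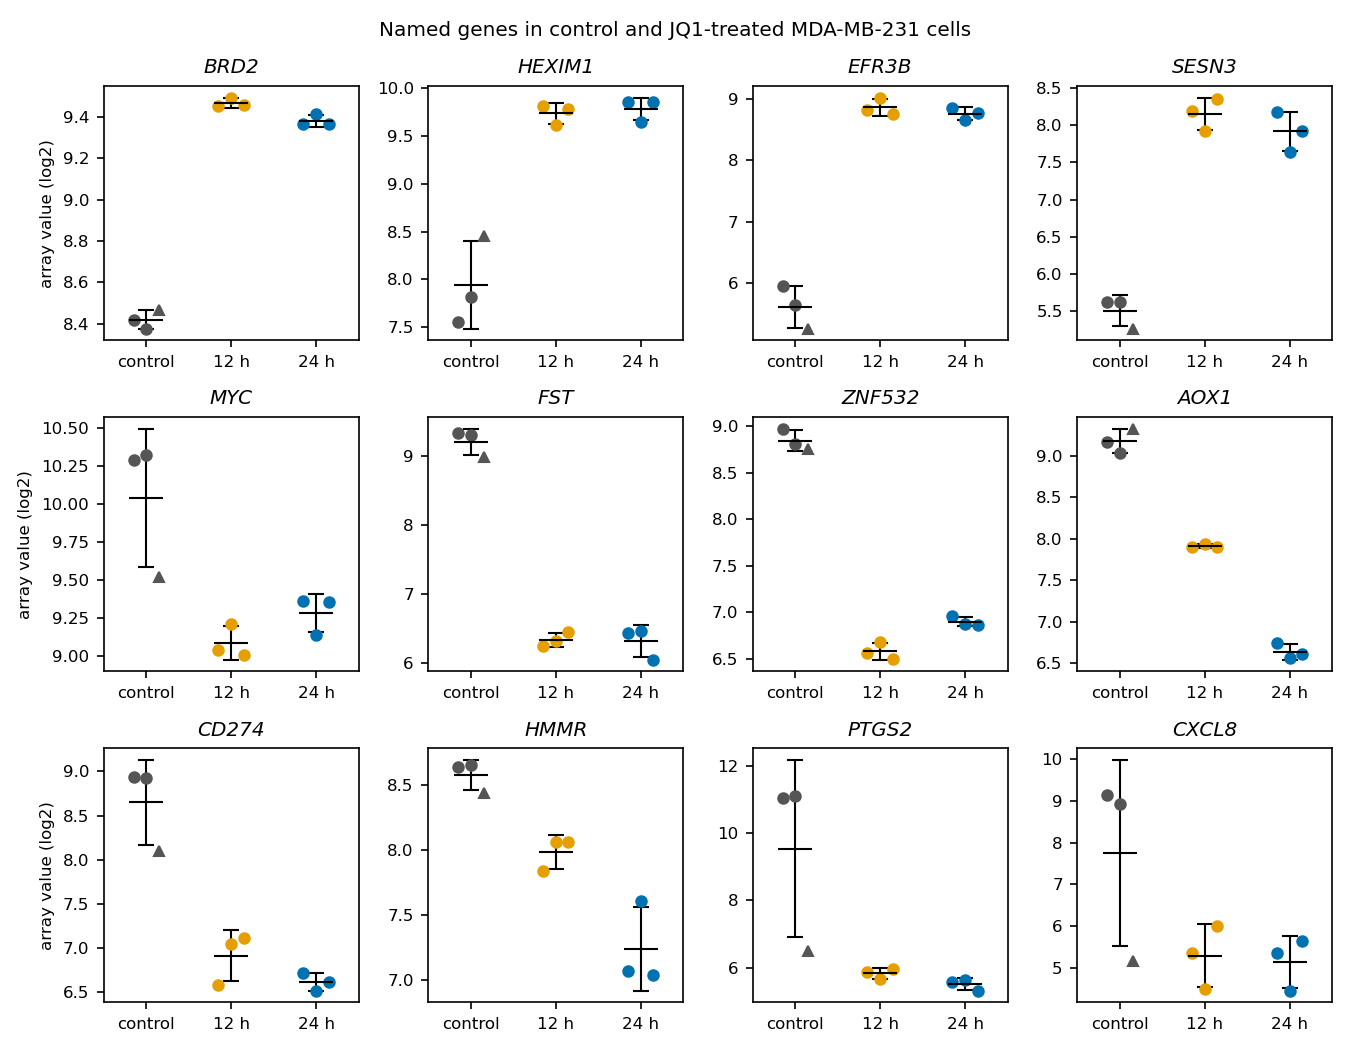
Log2 array values (y axis, a different range in each panel) of 12 named genes in control, JQ1 12 h and JQ1 24 h arrays (x axis), with 1 point per array, bars for mean ± SD of 3 arrays, and control 3 as a triangle. Control 3 lies with the other controls for BRD2, FST, ZNF532 and AOX1, and near the treated arrays for PTGS2 and CXCL8.

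After 24 h many of the same genes were called, and the mitosis list was called down. EFR3B was again the highest (8.76 ± 0.10, 8.87-fold, log2 3.15, SE 0.16, adjusted p = 2.4e-05), followed by SESN3 (log2 2.41), PEG10 (2.35) and MT1E (2.34). HEXIM1 was up 3.57-fold (log2 1.84, SE 0.20, adjusted p = 0.00098) and BRD2 1.95-fold (log2 0.96, SE 0.06, adjusted p = 9.8e-05). The aldehyde oxidase gene AOX1 fell from 9.18 ± 0.15 to 6.64 ± 0.10, 5.82-fold lower (log2 −2.54, SE 0.09, adjusted p = 5.2e-06), and the keratin-associated gene KRTAP2-3 from 11.88 ± 0.12 to 8.85 ± 0.31 (log2 −3.02, SE 0.15, adjusted p = 2.4e-05). PTGS2, the gene of cyclooxygenase 2, had the lowest log2 difference (−4.03, SE 1.02, adjusted p = 0.034). Its control values were 11.05, 11.09 and 6.49, so that its control SD was 2.64, and it lost the call when any array but control 3 was left out (adjusted p up to 0.12).

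The remaining genes among the 10 highest at 24 h were ZDHHC12-DT (log2 2.12), PCYOX1 (1.70), TRNP1 (1.65), GXYLT2 (1.65) and MIDN (1.61). The remaining falls were those of TNC (−3.35), FST (−2.88), RDUR (−2.75), the anti-apoptotic gene BCL2A1 (−2.50), EPB41L3 (−2.42), TM4SF18 (−2.35) and LIF (−2.32). Their adjusted p-values ran from 2.0e-05 for FST to 0.015 for LIF. Of 82 genes named and called at 24 h, 45 kept the call whichever array was left out. LIF lost it without control 1, control 2 or JQ1 24 h replicates 2 or 3 (adjusted p up to 0.057) and TNC without JQ1 24 h replicate 3 (0.051). MYC was 1.70-fold lower (log2 −0.76, SE 0.19, adjusted p = 0.036), a call lost without any array but control 3 (up to 0.12), and at −1.02 without control 3. CCND1, the G1 cyclin, rose (log2 0.67, SE 0.11, adjusted p = 0.0067). The mesenchymal regulator ZEB1 fell slightly (−0.46, adjusted p = 0.042), lost without any array but control 3 (up to 0.15). BCL2L11 (0.64, adjusted p = 0.086), CXCL8 (−2.61, 0.12), FOXM1 (−0.62, 0.15), FOSL1 (0.35, 0.066), BCL2L1 (0.12, 0.50), E2F1 (0.22, 0.53), BRD3 (0.03, 0.88) and VIM (0.30, 0.056) did not pass the test. CXCL8, BCL2L11, E2F1 and VIM were called without control 3, and FOSL1 was called without JQ1 24 h replicate 3.

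At 24 h 1714 genes were called, 770 up and 944 down, and 250 changed at least 2-fold (83 up, 167 down). The groups did not overlap for 26.1% of genes, against 10% by chance. Without control 3 the count was 3111 (1430 up, 1681 down), which included 1640 of the 1714. Without control 1 or control 2 it was 1011 or 1034, and without JQ1 24 h replicate 1 or 3 it was 914 or 786.

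Mitosis and G2/M genes shifted down at 24 h (median log2 −0.68 over 32 members, camera adjusted p = 7.6e-12, and adjusted p = 0.53 with an estimated correlation). Of these 14 fell and 0 rose, or 23 and 0 adjusted over the list alone. They included the spindle protein HMMR (log2 −1.34, SE 0.15), the kinetochore gene NDC80 (−1.35), the midzone gene PRC1 (−1.06), separase (ESPL1, −0.79) and the kinase AURKA (−0.89, adjusted p = 0.020, lost without JQ1 24 h replicate 1 or 3, up to 0.085). The fall was seen most in replicates 1 and 3 of the 24 h group. The median member's distance from its mean over the 9 arrays was −0.53 and −0.69 in them and −0.04 in replicate 2, against 0.05, 0.02 and 0.61 in controls 1, 2 and 3. The list stayed past the threshold when any array was left out, and without control 3 15 members fell and 1 rose (median −0.48).

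Lists for DNA replication (median −0.37 over 26 members, adjusted p = 0.011) and homologous recombination (median −0.47 over 15, adjusted p = 0.0029) were also called down, with adjusted p = 0.71 and adjusted p = 0.58 with an estimated correlation. GINS3 (log2 −0.85) and CDC6 (−0.76) fell and CCND1 rose in the first, and RAD51AP1 (−1.36) and PALB2 (−0.65, adjusted p = 0.0496, up to 0.17 and kept only without JQ1 12 h replicates 1 or 2) fell in the second. The counts were 2 down and 1 up (3 and 1 adjusted over the list alone) and 2 down and 0 up (3 and 0). Control 3 was higher than controls 1 and 2 in both lists, by medians of 1.16 and 0.89. Without control 3 the replication list's direction turned (median 0.05, adjusted p = 0.58) and the recombination list's call was lost (adjusted p = 0.48). The replication list's call was also lost without JQ1 24 h replicate 3 (0.063).

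The MYC list was down at 24 h (median −0.31, adjusted p = 0.00023, and adjusted p = 0.53 with an estimated correlation), with 7 members down and 1 up, the same adjusted over the list alone. RRP12 (log2 −0.67), CDK4 (−0.61) and the nucleolar gene NOP58 (−0.59) fell. Control 3 was higher on this list by 0.52, and without it the list's median was −0.14 and its adjusted p 0.049, with 7 members down and 1 up. The NF-kB and cytokine list was down (median −0.58, adjusted p = 0.00011, and adjusted p = 0.54 with an estimated correlation), with 5 members down and 0 up (7 and 0 adjusted over the list alone), including the chemokine CCL20 (−1.65), NFKB1 (−0.69) and PTGS2. The integrated stress response list was down (median −0.69, adjusted p = 0.00036, and adjusted p = 0.57 with an estimated correlation), with 4 down and 0 up (6 and 0 adjusted over the list alone), namely PSAT1 (−1.42), XBP1 (−1.58), SHMT2 (−0.54) and TRIB3 (−1.97). Control 3 was lower than controls 1 and 2 by medians of 1.13 on the cytokine list and 1.58 on the stress list. Without control 3 the medians of these lists were −0.90 and −1.38, with 15 and 13 members down and 0 and 1 up.

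The apoptosis list was called down at 24 h (median −0.17 over 17 members, adjusted p = 0.045, and adjusted p = 0.53 with an estimated correlation), with 5 down and 1 up (6 and 3 adjusted over the list alone). Members that fell included BCL2A1, XIAP (log2 −0.69), BIRC2 (−0.53) and CFLAR (−0.80), which all restrain cell death. The call was lost without control 1, control 3, JQ1 12 h replicate 2 or JQ1 24 h replicates 2 or 3 (adjusted p up to 0.12). The p53 list was up (median 0.54, adjusted p = 0.0042, and adjusted p = 0.53 with an estimated correlation) with 5 members up and 0 down by either adjustment, among them SESN3, CCNG1 (0.51) and PLK3 (0.58); without control 3 its median was 0.38 and its adjusted p 0.099, with 5 members up and 1 down. Hypoxia and glycolysis genes were up (median 0.50, adjusted p = 0.00036, and adjusted p = 0.53 with an estimated correlation), with 4 up and 0 down (9 and 2 adjusted over the list alone). Those called were BNIP3 (0.89), GAPDH (0.59), ADM (0.79) and LDHA (0.50), while VEGFA again lay below controls 1 and 2 without a call. Without control 3 the list's median was 0.30 and its adjusted p 0.0097, with 6 members up and 2 down. Cholesterol genes were up (median 0.22, adjusted p = 0.011, and adjusted p = 0.58 with an estimated correlation) with MVD (0.75), TM7SF2 (0.73) and INSIG1 (1.35) called by either adjustment. Without control 3 this list's median was 0.42 and its adjusted p 7.4e-07 at the preset correlation, with 11 members up. Its adjusted p was 0.082 without control 2. Autophagy and lysosome genes were up (median 0.18 over 20, adjusted p = 0.042, and adjusted p = 0.58 with an estimated correlation) with GABARAPL2 (0.69) and CTSA (0.48) called and 3 members adjusted over the list alone. That call was lost without control 3 or JQ1 24 h replicates 1 or 3 (adjusted p up to 0.48).

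The other 10 lists were not called at 24 h. CD274 was 4.09-fold lower (log2 −2.03, SE 0.23, adjusted p = 0.0012), in an interferon-stimulated list with 6 members down and 0 up (6 and 1 adjusted over the list alone, camera adjusted p = 0.14). In the AP-1 list 5 rose and 1 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.23), led by KLF2 (1.22), DUSP4 (0.93) and JUND (1.32). This list was called up without control 1 or control 2 (0.030 and 0.042 at the preset correlation, and 0.79 with all arrays and an estimated correlation), while without control 3 its direction turned down without a call (median −0.21, adjusted p = 0.25, 9 members down and 5 up). Among mesenchymal genes (camera adjusted p = 0.18) 5 fell and 1 rose, 5 and 2 adjusted over the list alone, including TNC, LOX (−1.47) and ZEB2 (−0.34). TIMP2 (0.95) rose in the matrix protease list (3 up and 1 down over all genes, 3 and 3 adjusted over the list alone, camera adjusted p = 0.49, 0.041 without control 3, and 0.78 with all arrays and an estimated correlation). Camera adjusted p-values were 0.18 for the BET family (2 up and 0 down by either adjustment, fry adjusted p = 0.0033), 0.74 for epithelial genes (3 up and 3 down, 6 and 4 adjusted over the list alone), 0.44 for integrins (1 up and 1 down, 3 and 1), 0.74 for YAP targets (3 up and 1 down, 4 and 5), 0.54 for leukocyte markers (0 called by either adjustment) and 0.18 for housekeeping genes (1 up, 2 adjusted over the list alone). In a single direction fry called the MYC (0.041), apoptosis (0.015), p53 (0.027) and hypoxia (0.0069) lists at 24 h beside the BET family, while the mitosis list was at 0.055. In its mixed form most lists passed at 24 h, mitosis (fry adjusted p = 0.0051) and housekeeping genes (1.2e-05) among them. Those that did not were DNA replication (0.061), homologous recombination (0.098), the stress response (0.055) and leukocyte markers (0.53). In fry 0 lists were called between 24 h and 12 h, where the mitosis list had an adjusted p of 0.19.

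**Figure D3:**
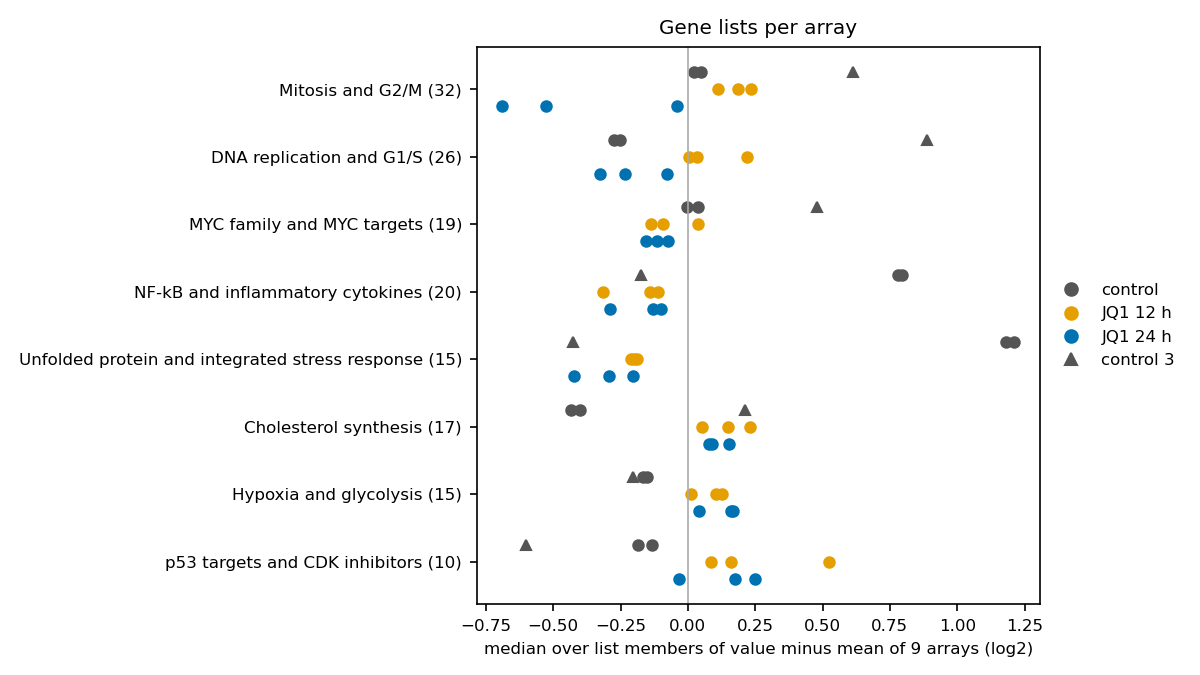
Median over the members of 8 gene lists (member counts in brackets on the y axis) of each gene's log2 value minus its mean over the 9 arrays (x axis), with 1 point per array coloured by group and control 3 as a triangle. Control 3 lies away from controls 1 and 2 on the cell cycle, MYC, cytokine, stress response, cholesterol and p53 lists, and near them on the hypoxia list. On the mitosis list, 2 of the 3 JQ1 24 h arrays lie lowest.

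Comparing the treated groups directly, AOX1 was the only gene called between 24 h and 12 h (log2 −1.28, SE 0.09, adjusted p = 0.0024). Its values were 7.92 ± 0.02 at 12 h and 6.64 ± 0.10 at 24 h. Limma called 0 genes up, and 995 genes had an unadjusted p under 0.05. The direct comparison uses the controls only for the estimate of the spread, and 22 genes were called without control 3 (7 up, 15 down), 5 without JQ1 24 h replicate 2 and 2 without JQ1 24 h replicate 3; the linear model without moderation called 0. As lists, mitosis (median −0.67, adjusted p = 8.9e-30), DNA replication (−0.37, adjusted p = 3.8e-05) and homologous recombination (−0.43, adjusted p = 3.8e-05) were lower at 24 h than at 12 h, and integrins (0.17, adjusted p = 0.036) and autophagy genes (0.09, adjusted p = 0.049) were higher. With an estimated correlation these were adjusted p = 0.34, adjusted p = 0.67, adjusted p = 0.67, adjusted p = 0.34 and adjusted p = 0.67. Over all genes 0 members of these lists were called, and adjusted over the list alone 24 mitosis members fell and 2 integrin members rose, with 0 in the other 3 lists. KIF2C (log2 −0.73), HMMR (−0.75) and CDC20 (−0.81) had the lowest p in the mitosis list, with adjusted p-values of 0.29, 0.38 and 0.38 over all genes. The integrin call was lost without JQ1 12 h replicate 1 or JQ1 24 h replicate 1 (up to 0.13), and the autophagy call without JQ1 12 h replicates 1 or 2 or JQ1 24 h replicates 1 or 3 (up to 0.16).

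The changes at 12 h and 24 h overlapped. In the same direction at both times 978 genes were called (413 up, 565 down) and 0 in opposite directions, where independent lists of these sizes would share 68.7. Simulated data sets with no difference between groups give no measure of this overlap, since only 1 of 100 had any call. Log2 differences at the 2 times correlated at r = 0.89 across genes, which are not independent replicates. The simulated data sets gave a median of 0.51, a lowest value of −0.74 and a highest of 0.93. The covariance was 0.0970 against a simulated median of 0.00902. The shuffle could deal deviations of the controls to the treated groups with either sign. The simulated values therefore do not measure the effect of the shared controls alone, and no conclusion is drawn from them. The 3 controls are too few to split, so part of the overlap may come from them.

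**Figure D4:**
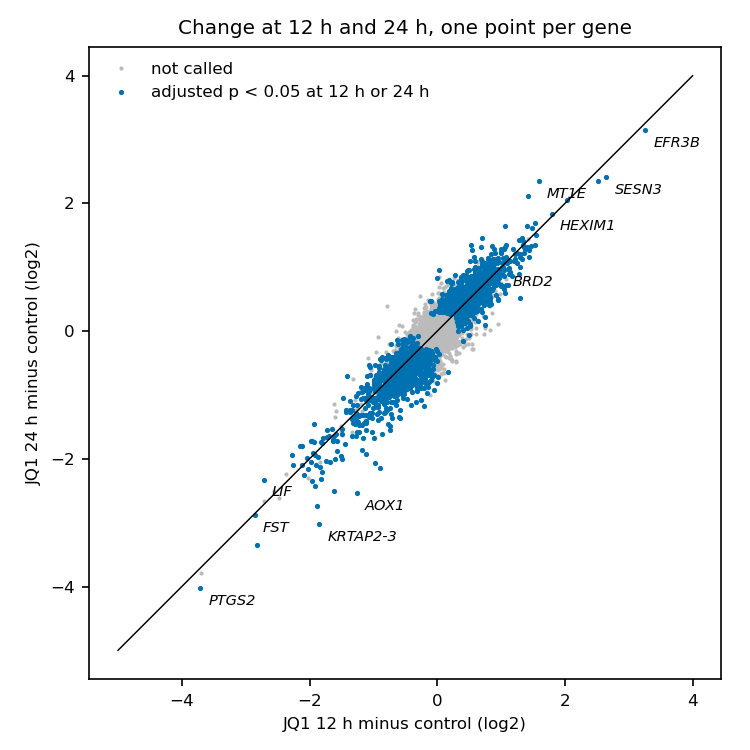
Log2 difference from control at 12 h (x axis) and 24 h (y axis) for 14884 genes, with genes called at either time in blue, the others in grey, and a line of equal change. Points follow the line (r = 0.89, with both axes sharing the 3 controls), and AOX1 and KRTAP2-3 lie below it.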

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

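The comparison of 24 h with 12 h was chosen in advance; no test in this part was chosen after its result was seen, though the mitosis values per array were. A result is listed here because its change from control differed between the 2 treatment times by a test of the difference itself. For AOX1 the difference of 24 h minus 12 h was −1.28 on the log2 scale (limma with Benjamini-Hochberg, adjusted p = 0.0024), with all 3 values at 24 h below all 3 at 12 h.

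For 5 gene lists the difference between the times passed camera at the preset correlation. The median over members of 24 h minus 12 h was −0.37 for DNA replication, −0.67 for mitosis, −0.43 for homologous recombination, 0.17 for integrins and 0.091 for autophagy and lysosome genes. With the correlation estimated from the data 0 of these 5 passed. The mitosis list medians, as distances from the mean over all arrays, were −0.53, −0.04 and −0.69 in JQ1 24 h replicates 1, 2 and 3, all below the 0.11, 0.24 and 0.19 of the JQ1 12 h replicates. No technical or biological explanation was tested for these differences.

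The count of genes called was set against other splits of the same 6 arrays into 3 and 3. For JQ1 12 h against control 1 of the 10 splits, the real one, called as many genes, with 1181 against a highest other of 0. For JQ1 24 h against control it was also 1 of 10 (1714 against 0), and for JQ1 24 h against JQ1 12 h 1 of 10 (1 against 0). Splits of 3 against 3 are too few for a share under 0.05. Every other split also mixed arrays of the 2 groups compared, so any difference between them widened the spread. Low counts in the other splits were thus partly fixed in advance, and no conclusion is drawn from them.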

How the results depend on the processing

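All alternatives here were fixed before the values were seen, except the counts of list members without control 3. Among named genes past the threshold in either the reported fit or the alternative, 0 changed direction in any alternative run; among those past it in neither, the direction changed in 20 cases over 12 results, AURKA and FOXM1 at 12 h among them. The share of called genes that rose stayed between 40.7% and 49.1% at 12 h and between 42.0% and 50.7% at 24 h.

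With array weights, JQ1 12 h against control gave 3498 genes (1718 up, 1780 down, 396 at least 2-fold), JQ1 24 h against control 3764 (1790, 1974, 412, with 7 lists), and JQ1 24 h against JQ1 12 h 14 (4 up, 10 down, 6 at least 2-fold). Without moderation the counts were 453 (213 up, 240 down, 96 at least 2-fold) at 12 h, 816 (377, 439, 160) at 24 h and 0 (0 down, 0 at least 2-fold) between the times. Fitting only the 2 groups compared, with fewer arrays to estimate the spread, gave 577 (266 up, 311 down) and 994 (441, 553), and 11 lists between the times. At an adjusted p under 0.01, a stricter threshold, there were 396 (164 up, 232 down) and 624 (280, 344), and 318 shared. With all rows of the table, which tests more features, 330 and 454 changed at least 2-fold at 12 h and 24 h, and 3 features were called between the times (3 down, 2 at least 2-fold). With an estimated correlation 0 lists were called in each comparison. Moderation with trend and robust estimation called 3 lists between the times. Where the construction of an alternative does not show it, the cause was not tested.

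Leaving out each array in turn gave 543 to 2986 genes at 12 h (234 to 1424 up, 305 to 1562 down, 118 to 424 at least 2-fold, 5 to 11 lists) and 786 to 3111 at 24 h (359 to 1430, 427 to 1681, 177 to 439, 7 to 11 lists). Between the times it gave 1 to 22 genes (0 to 7 up, 1 to 15 down, 1 to 4 at least 2-fold, 3 to 11 lists). The overlap of the 2 times ran from 460 to 2375 genes. The highest counts of genes came without control 3, the array that lies apart from its group. Between the times its removal left the log2 differences unchanged, so a changed estimate of the spread raised that count. For the comparisons with control, whether a smaller spread or larger differences raised the counts was not tested.

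The direction of 4 list results turned where the list passed the threshold in at least 1 of the 2 fits compared; it turned in 33 further cases over 13 results where it passed in neither. The DNA replication list at 12 h turned up with array weights (adjusted p = 0.0033) and without control 3 (2.4e-05), over a range of 2.4e-05 to 0.997 across alternatives and up to 0.895 with 1 array left out. Without control 3, homologous recombination at 12 h turned up (0.033, range 0.033 to 0.972), the AP-1 list at 12 h turned down (0.033, range 0.033 to 0.933, up to 0.895 with 1 array left out), and DNA replication at 24 h turned up without passing the threshold (0.577, range 6.4e-05 to 0.705). Control 3 differs from controls 1 and 2 on these lists in the direction that would hide the turned change.

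Quantile normalization, centring on the median, the filter on dim genes, the mean of all rows of a gene and moderation with trend and robust estimation left the number of genes called within 1.5 times of the reported count in all 3 comparisons. Over the leave-one-out fits, the named genes kept their side of the threshold in 2424 cases, lost the call in 322 and gained one in 44; the lists did so in 519, 20 and 24 cases.

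With the replicate number as a block the counts were 967 at 12 h (450 up, 517 down), 1478 at 24 h (694 up, 784 down) and 1 between the times, with 804 genes shared by the 2 times. The numbers do not appear to pair the arrays: deviations from the group means of arrays with the same number correlated at −0.32 to 0.22, while the highest values were between different numbers, control 3 with replicate 2 of JQ1 12 h (0.29) and of JQ1 24 h (0.28) and control 2 with JQ1 12 h replicate 1 (0.24). No background signal was given in the values used here, so what a low signal over background limits was not measured; the filter on dim genes gave 1303 and 1831 genes at 12 h and 24 h.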

Other observations

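The tests of control 3 were chosen after its distance from controls 1 and 2 was seen, as were the reading of the neighbour test against control 3 and the extra genes in the last paragraph; the neighbour test itself was planned.

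Control 3 lay apart from controls 1 and 2, with 462 of 14884 genes at least 2-fold different from their mean; a sample treated with JQ1 like the others but labelled as control would lie where the JQ1 arrays lie. The 410 genes used were called in the same direction at 12 h and 24 h without control 3. They were at least 2-fold apart between JQ1 arrays and controls 1 and 2. With 0 at the mean of those controls and 1 at the JQ1 mean, the median position of control 3 was 0.643. Single JQ1 arrays had medians of 0.938 to 1.02. For control 3, 72 genes lay under 0.25 and 168 above 0.75. Mixing of control RNA with RNA of treated cells would put genes near 1 share. On the linear scale the positions of control 3 had an interquartile range of 0.552, against at most 0.176 for a single JQ1 array. The JQ1 arrays helped to choose these genes and control 3 did not. Their positions near 1 and their narrow ranges were therefore partly fixed in advance. The spread of control 3 over these genes was not. A culture treated like the others would leave few genes at the control level, yet 72 lay under 0.25. Over all rows, without a choice of genes, the SDs of control 3 from the JQ1 arrays ran from 0.314 to 0.404. Those between JQ1 arrays reached 0.305. On the linear scale 69 genes lay under 0.25 and 187 above 0.75, where mixing allows 1 share. For these genes the values argue against such mislabelling and against mixing alone. A different intensity scale would move genes at the same level alike, but stress response genes differed from the DNA replication genes nearest in level by a median of −2.92 (SD 1.35 over 15 pairs, 14 below 0), in 2 lists picked because control 3 differed on them. A different growth state of the culture remains possible. The cytokine list was lower by a median of −1.13 and the cell cycle lists were higher. No value here measures growth, so this cannot be told apart from other causes that act on single genes.

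The position differed by gene. BRD2 (0.06), FST (0.11), ZNF532 (0.06), EFR3B (−0.18), SESN3 (−0.15) and AOX1 (−0.12) lay near controls 1 and 2, HEXIM1 (0.37) and CD274 (0.39) between, and CXCL8 (1.01), PTGS2 (0.85), INSIG1 (0.92) and TRIB3 (0.85) near the JQ1 arrays. MCM4 (1.79), CCNE1 (2.497) and DDIT4 (2.59), chosen after their values were seen, lay beyond them. Of 2375 genes called at both times without control 3, 728 (30.7%) had control 3 within the range of the 6 JQ1 arrays. Among the members called at both times without control 3, the median position was 1.08 for 13 of 15 stress response genes and 0.90 for 15 of 20 cytokine genes, so for many of these genes the contrast with JQ1 is a contrast with controls 1 and 2 alone.

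Genes that lie next to each other on a chromosome changed slightly alike. Over 6961 adjacent pairs that do not share the first 3 letters of their symbols the Spearman correlation of log2 differences was 0.0315 at 12 h (highest of 1000 shuffles of gene order 0.0326, p = 0.002) and 0.0473 at 24 h (highest shuffle 0.0371, p = 0.001, the smallest they can give). Probes shared between tandem gene copies were predicted to leave no correlation over such pairs. The 24 h value lies above all shuffles and the 12 h value at their edge. The filter goes by symbol alone, so copies with unlike symbols stay in and the values cannot decide on shared probes. By the prediction written beforehand, the 24 h value alone would have met co-regulation of neighbouring genes by the treatment. The same correlation was 0.0417 between control 3 and controls 1 and 2, which are all labelled as controls. The differences at 12 h and 24 h are taken from these same 3 controls, so control 3 enters them too. The value of 0.0417 is therefore no separate untreated reference, and the neighbour test was not run without control 3. The correlation at 12 h and 24 h may not come from JQ1, and these sources cannot be told apart.

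Some related genes outside the rule for named genes, chosen after their values were seen, changed beside those of the report. PDCD1LG2, the gene of the second PD-1 ligand, fell with CD274 (log2 −1.92 at 12 h and −1.74 at 24 h, adjusted p = 0.0020 at 12 h). CD80 (0.02 and 0.10) and CD276 (−0.36 and −0.12), read beside them, were not called, though CD276 was at 12 h without control 3 (−0.45). Of the genes read beside PER2, PER3 fell (−0.55 at both times), while PER1, CRY1, CRY2 and DBP were not called. Without control 3, PER1 and CRY1 were called down at both times. MT1X (0.78 and 0.82) and MT2A (0.50 and 0.54) rose beside MT1E, while MT1B, MT1F, MT1G, MT1H, MT1L and MT1M were not called (MT1L was called without control 3, at 0.42 and 0.44). TFPI (−1.60 and −2.01) and ESM1 (−1.94 and −1.91) fell beside THBD and EDN1, and the cochaperone gene BAG3 rose (0.49 and 0.53) beside HSPA1A and HSPA1B, as did HSPA1L (0.31 and 0.30). HSPH1, HSPB1, HSPD1 and HSPA6 were not called, but without control 3 HSPH1 was called up at both times (0.91 and 0.60) and HSPD1 at 12 h (0.52).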
